A study of Talpa occidentalis and Mus musculus with 35 samples.

How the data were processed

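The series covers 35 polyadenylated RNA libraries of mole and mouse gonads, prepared with standard Illumina protocols per the labels. The submitters' processing notes name STAR 2.6.1d and the mouse build mm9, with no role given for either, and the aligner settings and the counting step are not given in the sources used here. The file analysed here is an annotation of the mole assembly talOcc3 in feature format. It holds positions and a score, and no column belongs to a library. The number of columns of per-sample values left unused was 0. The differential expression planned before the data were examined was therefore not run, and the library depth is unknown. Groups were taken from sample titles, because the strain labels of the 4 libraries of the Fgf9 mutant comparison differ from one another in a running number.

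The start and end of each feature are 1-based positions on talOcc3 scaffolds as deposited. The score was deposited by the authors on transcript models, together with the interval of a named reference transcript and the highest score of the same symbol; what the score counts is not given in the sources used here. It was used as a percent of that highest score, to choose the best locus of a symbol and, in the closing section, per aligned base of the reference transcript. How the EVM, exonerate and ALN models were made is not given in the sources used here beyond those labels.

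Each gene line was joined to its transcript and coding parts in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Gene lines reached beyond their transcript in 412 cases, and the gene line was used for positions. A trailing copy suffix or low-confidence mark was removed from the name, so that loci of a symbol could be counted. Lines without a symbol counted as neighbours only. Copies were called tandem when on the same scaffold with at most 10 other loci between them. Space was the distance to the nearest non-overlapping locus on each side, summed, and other loci of the same symbol counted as neighbours. Percentiles came from 10000 random lists of the same size, drawn with replacement from named genes in the same of 10 equal classes of coding length, with ties counted equally to each side; gene order used lists without matching. They describe genes, which are not replicates, and a list is called outside the middle 95% when it lies beyond the central 95% of the random lists; members without a locus do not enter. Intervals of shares are exact binomial and those of medians come from order statistics.

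Mouse genes were protein-coding genes of GENCODE M21 (GRCm38), taken as coding spans. No coordinate was converted between builds. The later mole assembly MPIMG_talOcc4v2.1 was used only for names and for which genes neighbour each other; its sequence boundaries were inferred from where the start positions fall back, and its strand was not used.

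The steps were tested on simulated data. Over 13825 genes, all 200 adjacencies broken by 100 inversions were found and 0 others, and all 200 symbols given a tandem locus were found. Over 15954 genes, lists of 25 whose spaces were multiplied by 1, 2 and 4 lay above the middle 95% in 3, 52 and 97 of 100 lists, so a doubling of space was missed in about as many lists as it was found.

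The gene lists and the rule for named genes were fixed before the data were examined: FGF9 and CYP17A1 with the 5 nearest loci on each side, list members at 0 or several loci, the 3 members with most and the 3 with least space, the 10 symbols with most tandem loci, and members losing both neighbours. FGF9 and CYP17A1 were chosen from knowledge of the study. A few genes that the rule or the gene order would name are not reported here. Alternatives covered names as written, tandem distance, coding length, scaffold size, strand and kind of neighbours, the larger side, matching, orientation and the distance allowed between pairs. A score of at least 50% of the highest, more than 1 exon, and for space the genes named once in both species were added after seeing the data.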

Results

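The series sequenced polyadenylated RNA from gonads of the Iberian mole, Talpa occidentalis, and of the mouse, and its labels set out a search for genes behind the ovotestis, the gonad with an ovarian and a testicular part that female moles carry. The labels described 35 libraries in 16 groups, 19 from moles and 16 from mice. Mole ovotestis and testis were sampled at embryonic day 15 (2 libraries each), and the ovarian part, the testicular part and the testis at postnatal day 7 (3 each) and in adults (2 each). Mouse ovary and testis of the CD1 strain were sampled at embryonic day 13.5, postnatal day 7 and 10 weeks, with 2 libraries per group. Ovaries of an Fgf9 mutant and of wild-type B6 embryos were sampled at embryonic day 13.5, again with 2 each. The file analysed here was the annotation of the mole genome, assembly talOcc3. It carried no value per library, so the expression contrasts between these groups were not analysed here, the depth of the libraries is unknown, and the results below describe gene models. Such a model set has no replicates. Intervals and random gene lists describe genes and not animals.

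The annotation held 23336 gene lines on 2074 scaffolds, each with 1 transcript, and 180386 coding parts. The median gene had 5 exons (quartiles 2 and 10), a coding length of 1011 bases (quartiles 597 and 1737) and a span of 7029 bases. The coding length was a multiple of 3 in 20483 transcripts, 87.8% of them, and exon and coding lines were the same in every transcript, so the models held no untranslated parts. A gene symbol stood on 21490 lines, and 1846 lines had none. Models labelled EVM made up 14981 lines with a median of 8 exons, and 0.494% of them had a single exon. Models labelled exonerate made up 5944 lines, of which 79.4% had a single exon, and those labelled ALN made up 2411 lines, of which 40.5% did. On the 57 scaffolds whose last annotated base lay at 1000000 or beyond, the median coding length was 1104 bases and the median exon number 6.

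FGF9, a secreted growth factor required for testis development in mice, was annotated at a single locus of talOcc3, on scaffold 38 from 11731991 to 11761319 on the minus strand, with 3 exons and a coding length of 624 bases. The labels name an Fgf9 mutant mouse and the series title speaks of regulatory rearrangements, so the question was whether the neighbours of FGF9 were those of the mouse gene. On one side the order was shared. MICU2 lay 132 kb away in the mole, from 11893652 to 11939441, followed by ZDHHC20, MRPL57, SKA3 and SAP18. The same 5 genes followed Fgf9 in the same order in the mouse (GRCm38, chromosome 14, coding span 58073056 to 58109575), where Micu2 lay 73.8 kb away. All 5 genes, and FGF9 itself, were on the opposite strand in the mole file from the strand in the mouse.

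On the other side the neighbours differed. The nearest locus in the mole was RUBCNL, from 10381222 to 10406007 on the plus strand, with 1326 kb of scaffold between it and FGF9 and no other analysed gene model in that interval. LRCH1, ESD, HTR2A, which encodes a serotonin receptor, and CCDC59 came next. In the mouse the nearest coding gene on that side was 1700129C05Rik at 1024 kb, then Gm5142 and Rcbtb1, and Rubcnl lay 16.9 Mb from Fgf9 with 105 genes named once in both annotations in between. Mole RCBTB1 lay on scaffold 38 as well, 3.95 Mb from FGF9, from 7737742 to 7779429. SETDB2, CAB39L and CDADC1, the genes after Rcbtb1 in the mouse among those named once in both, followed it on scaffold 38. Their order among themselves was kept, but its direction toward FGF9 was not. In the mouse they ran away from Fgf9 and in the mole toward FGF9, with RCBTB1 the farthest. RUBCNL and the genes from RCBTB1 to CDADC1 were on the same strand in both species, unlike FGF9 and the genes from MICU2 to SAP18. SHISA2, AMER2, SPATA13 and MIPEP, which come next in the mouse, lay on scaffold 6. In the later mole assembly MPIMG_talOcc4v2.1, RUBCNL and FGF9 had 0 protein-coding loci and 4 long non-coding RNA loci between them, and FGF9 and MICU2 had 0 protein-coding loci between them.

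**Figure D1:**
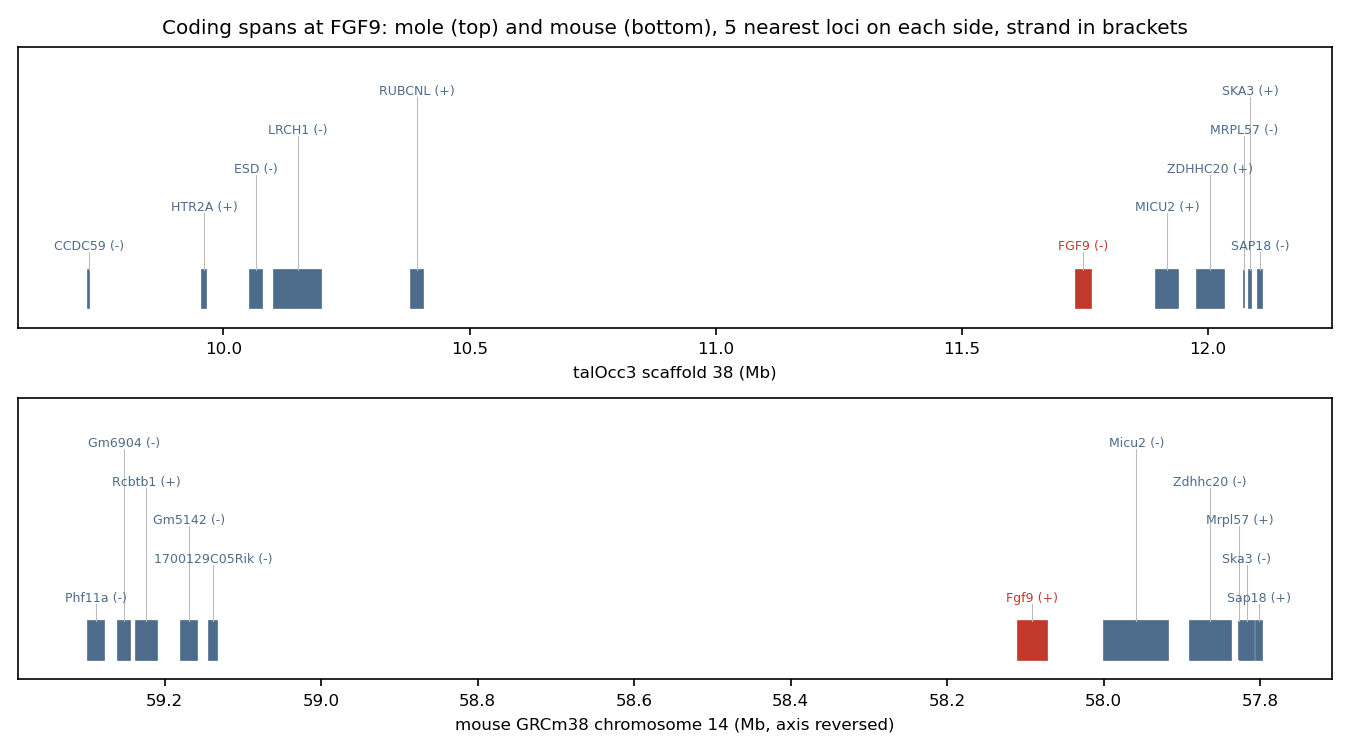
Gene models around FGF9 in the mole (top, talOcc3 scaffold 38) and mouse (bottom, GRCm38 chromosome 14, axis reversed), with position in Mb on the horizontal axes, boxes for gene spans, strand in brackets and FGF9 in red. MICU2, ZDHHC20, MRPL57, SKA3 and SAP18 lie to the right of FGF9 in both, while the wide gap to the left, 1326 kb in the mole and 1024 kb in the mouse, ends at RUBCNL in the mole and at 1700129C05Rik in the mouse.

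CYP17A1 encodes the enzyme with hydroxylase and lyase activity that commits steroids to androgen synthesis. It was annotated at 3 loci side by side on talOcc3 scaffold 11, all on the minus strand. The model from 45139044 to 45144553 had 8 exons, a coding length of 1533 bases and the highest score of that symbol, 1476. A second model, from 45100228 to 45105611, also had 8 exons and 1533 coding bases, covered the same interval of the reference transcript (173 to 1696) and reached 92.5% of the highest score. The model between them, from 45117841 to 45121591, had 6 exons and 1011 coding bases, covered the reference transcript from position 698 on and reached 61.2%. The loci were 12.2 and 17.5 kb apart.

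The genes around CYP17A1 kept the mouse order. WBP1L, SFXN2, ARL3, TRIM8 and SUFU lay on one side in both species, and BORCS7, AS3MT, CNNM2 and NT5C2 on the other. The mouse annotation (GRCm38, chromosome 19) had 1 Cyp17a1 locus there, with a coding span from 46667328 to 46672843. The mole file had 1 further model in the interval, a locus named TUBA1B with 2 exons and 533 coding bases that overlapped BORCS7. Between WBP1L and BORCS7 the mole had 72.2 kb and the mouse 35.2 kb. The gaps outside the loci were 11.3 kb to WBP1L and 15.8 kb to the TUBA1B locus in the mole, and 12.6 kb to Wbp1l and 17.1 kb to Borcs7 in the mouse.

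**Figure D2:**
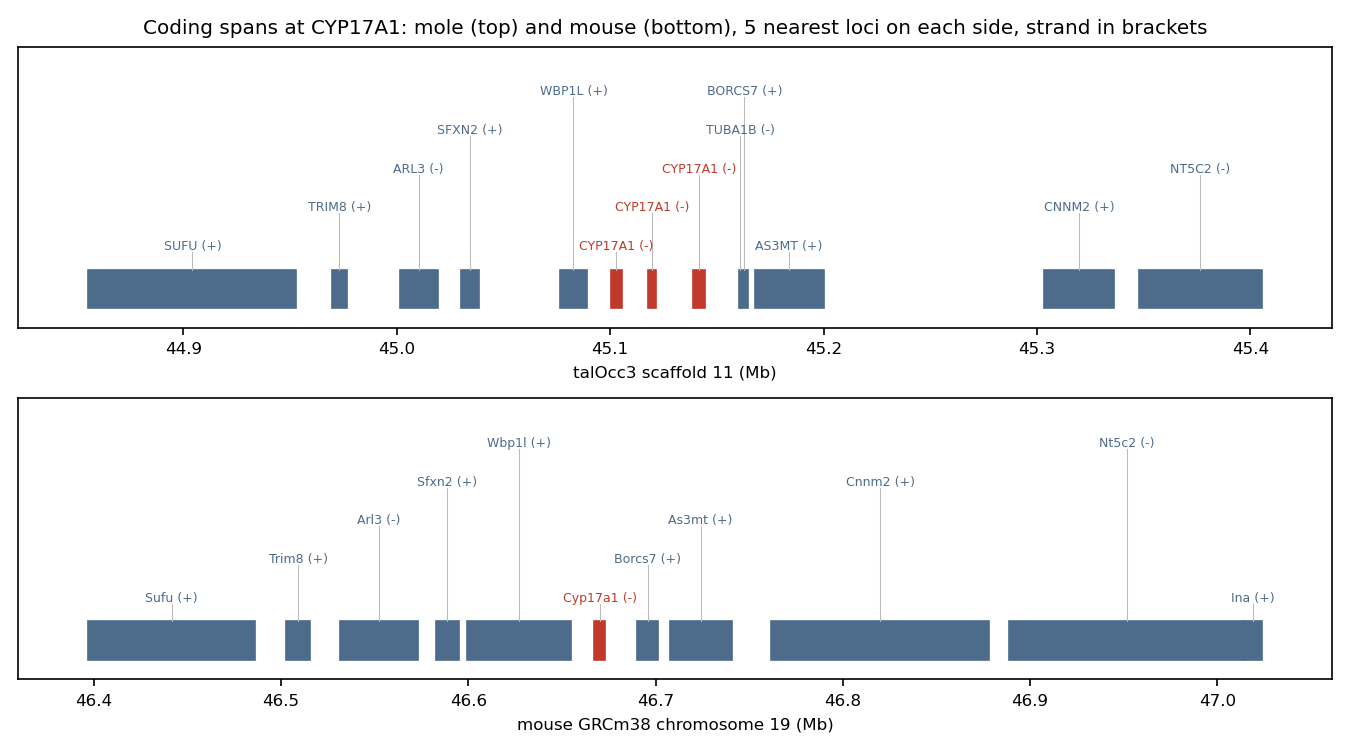
Gene models around CYP17A1 in the mole (top, talOcc3 scaffold 11) and mouse (bottom, GRCm38 chromosome 19), with position in Mb on the horizontal axes, boxes for gene spans, strand in brackets and CYP17A1 in red. The mole has 3 loci and the mouse 1 between WBP1L and BORCS7.

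Space around genes asked whether the gonad genes sit in wide stretches without other genes, where distant regulatory sequence can lie. Ovary and granulosa genes had a median of 259 kb to the nearest loci, both sides summed (95% order-statistic interval 143 to 508 kb, n = 20 genes), above all 10000 random lists matched on coding length, whose median was 48.3 kb. NR2F2, a nuclear receptor of the gonadal interstitium, had 2643 kb, BMP2 1357 kb and INHBA, the activin beta A subunit, 1128 kb. HSD17B1, an enzyme of estradiol synthesis, had 1.64 kb, INHA 15.4 kb and the anti-Müllerian hormone receptor AMHR2 27.3 kb. Testis and Sertoli genes had a median of 150 kb (interval 74.9 to 523 kb, n = 22 genes, percentile 99.8 among random lists). SOX9, the transcription factor that drives Sertoli cell differentiation, had 1808 kb, FGF9 1458 kb and ZFPM2 1192 kb, against 18.1 kb for AMH, 19.4 kb for CBX2 and 48.2 kb for CLDN11. FGF ligands had a median of 189 kb (interval 52.9 to 497 kb, n = 19 genes, percentile 99.97). FGF9, FGF12 with 663 kb and FGF10 with 579 kb had the most, and FGF11 with 5.59 kb, FGF22 with 8.17 kb and FGF21 with 28.0 kb the least.

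The other 3 lists lay within the middle 95% of random lists over all their members. Leydig and steroidogenesis genes had a median of 74.9 kb (n = 23 genes, percentile 86.9), with 628 kb at the hedgehog receptor PTCH1 and 407 kb at PDGFRA, and 4.11 kb at CYP21A2 and 6.395 kb at INSL3, with HSD17B1 lowest at the value above. That call depended on the genes entered: over the 19 members named once in both the mole and the mouse annotation the median was 141 kb and the percentile 99.2, a gene set chosen after seeing the data, and with neighbours on the same strand only the percentile was 49.5. Germ cell and meiosis genes had a median of 35.7 kb (n = 29 genes, percentile 14.2). KIT, the stem cell factor receptor, had 457 kb, TNP1 386 kb and BMP15 342 kb, whereas the meiotic cohesin REC8 had 0.396 kb, DND1 0.982 kb and SYCP3 3.95 kb. Markers of endothelium, blood, immune cells and smooth muscle had a median of 34.6 kb (n = 13 genes, percentile 18.2). PTPRC had 1095 kb, KDR 254 kb and PECAM1 114 kb, against 2.395 kb for CSF1R, 3.41 kb for CD68 and 4.24 kb for TAGLN. The nearest locus on 1 side of CSF1R, 0.678 kb away, was its own second model. Over all 15954 named genes with a neighbour on both sides the median was 49.9 kb, and 242 genes without a neighbour on one side were left out, none of them on a list. Counting only neighbours on the same strand gave wider medians, 680 kb for ovary, 498 kb for testis, 326 kb for FGF, 141 kb for Leydig and 99.3 kb for germ cell genes and 133 kb for markers of other cell types, and for these markers the larger side alone gave 18.5 kb.

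**Figure D3:**
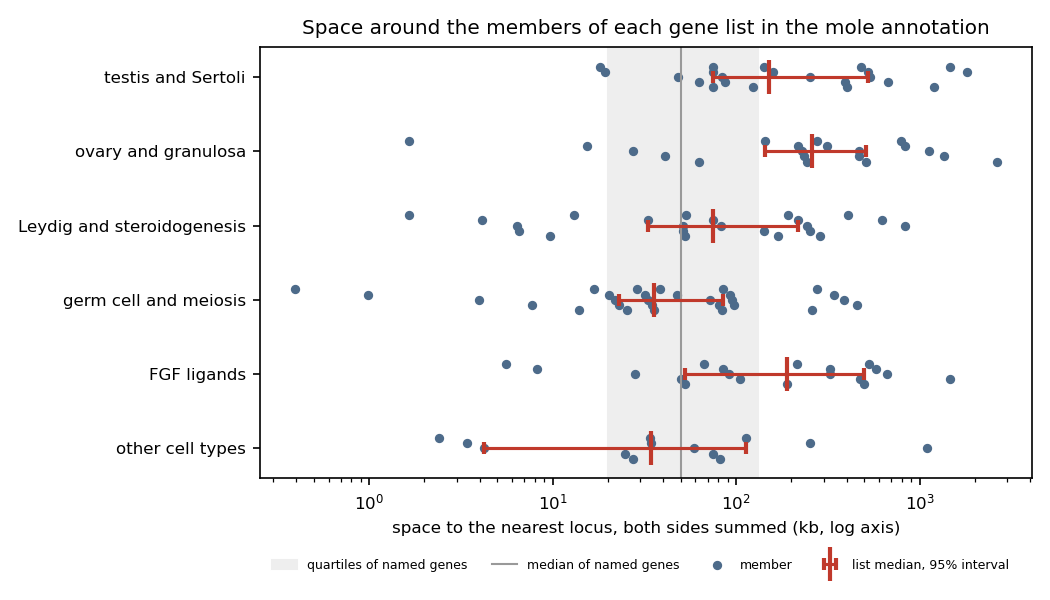
Space to the nearest locus on both sides summed (kb, log axis) for the members of each gene list in the mole annotation; points are genes, red bars the list median with its 95% interval, and the grey band and line the quartiles and median of all named genes. Ovary and granulosa genes have a median of 259 kb, testis and Sertoli genes 150 kb and FGF ligands 189 kb, against 49.9 kb over all named genes.

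Most gonad genes were annotated at 1 locus. Of the 16196 symbols in the file, 2371 (14.6%) had more than 1 locus. The percentiles below rank the share among list members with a locus, while the counts are out of all members. That share was 13.0% in the Leydig list, 9.09% in the testis list, 6.90% in the germ cell list and 7.69% among markers of other cell types. In the Leydig and steroidogenesis list 3 of 25 members did, which was percentile 42.5 among random lists. These were CYP17A1, CYB5A, the cytochrome b5 that assists its lyase reaction, and HSD11B1. The CYB5A locus of highest score, on scaffold 3, was a single exon. The other CYB5A locus, on scaffold 41, had 2 exons and 81.3% of the highest score. The 2 HSD11B1 loci lay on the same strand of scaffold 35, the lesser at 36.5% of the highest score. They covered the reference transcript from 67 to 678 and from 673 to 963, so they were not shown to be 2 copies of the gene. In the testis and Sertoli list 2 of 25 did (percentile 25.8), SOX10, whose second model lay on a scaffold with its last annotated base at 871, and ETV5, whose second model was a single exon at 19.6% of the highest score. In the germ cell and meiosis list 2 of 34 did (percentile 16.5). The pluripotency factor NANOG had 7 loci on 6 scaffolds, the one of highest score on scaffold 7, and PIWIL1 had 2 on scaffold 27. The next NANOG model, at 81.5% of the highest score, lay on a scaffold with its last annotated base at 4983. The remaining NANOG models reached 14.2 to 45.1%, and the second PIWIL1 model 15.2%. CSF1R was the 1 of 15 markers of other cell types (percentile 25.7), with a second model of 4 exons next to the first. The 2 CSF1R models, on the same strand, covered reference positions 273 to 929 and 1091 to 3195. They too were not shown to be 2 copies of the gene. No member of the ovary and granulosa list (22 genes, percentile 2.21) or of the FGF ligands (22 genes, percentile 1.84) had several loci. No share can be lower, so these percentiles consist only of tied random lists, with ties split equally to each side. With ties counted in full, neither list lay below the middle 95%. With ties split, neither stayed below it when loci of under 300 coding bases were left out (3.31 and 3.27).

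Several members had no locus under their symbol. These were SOX8, PTGDS and DHH of the testis list, FOXL2 and IRX3 of the ovary list, CYP11B1 and HSD3B2 of the Leydig list, NANOS2, PIWIL4, PRM1, PRM2 and ZP4 of the germ cell list, FGF2, FGF3 and FGF19 of the FGF ligands, and HBA1 and HBB among the markers of other cell types. The models without a symbol were not searched for them, so these genes were not analysed here rather than shown to be missing from the genome.

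Tandem loci were led by TRIM38 and olfactory receptors. Loci of 1 symbol within 10 other loci of each other were found for 1349 symbols, and of the 10 symbols with most such loci 7 were olfactory receptors. TRIM38 had 55 tandem loci, OR7A10 41, OR6C2 34, OR14A16 29 and BMS1P20 28, followed by OR8D4 with 17, OR2A2 and OR2L13 with 16 each, and LOC107986994 and OR1J4 with 14 each. Of the 5294 loci beyond the best of each symbol 54.5% had a single exon, against 8.77% of the best loci.

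Gene order around the gonad genes was mostly that of the mouse. Among 12410 genes named once in both annotations, 11433 of 12295 adjacent mole pairs were adjacent with the same relative orientation in the mouse, 93.0% (exact 95% interval 92.5 to 93.4%). Every ovary and granulosa gene (20 genes) and every Leydig and steroidogenesis gene (19 genes) with neighbours on both sides kept both, at percentiles 95.8 and 95.3 among random lists. In the testis and Sertoli list 16 of 20 kept both (percentile 24.1), and FGF9, MAP3K4, CYP26B1 and FSHR, the follicle-stimulating hormone receptor, kept 1. Among FGF ligands 14 of 19 kept both (percentile 10.8), and FGF4, FGF9, FGF14, FGF17 and FGF20 kept 1. In the germ cell list 23 of 25 did (percentile 74.2), with BMP15 and FIGLA keeping 1, and among markers of other cell types 9 of 12 (percentile 18.0), with CDH5, PTPRC and ADGRE1 keeping 1. The genes keeping 1 neighbour were named after their values were seen. No member lost both neighbours, which 283 of 12223 genes did. None of these 6 percentiles lay outside the middle 95% of random lists.

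Against the later mole assembly MPIMG_talOcc4v2.1, for which strand was not used, 11650 of 12085 adjacent pairs were adjacent (96.4%, interval 96.1 to 96.7%). Neighbours were taken among genes named once in both mole annotations, and so were not always those of the mouse comparison. FGF9 kept RUBCNL and MICU2, and both neighbours were also kept by FGF14, FGF20, BMP15 and FIGLA. MAP3K4 and FSHR in the testis list and FGF4 and FGF17 among FGF ligands kept 1, and no member of the other 4 lists lost a neighbour. For MAP3K4, FSHR, FGF4 and FGF17 the neighbour lost was the one also lost against the mouse. Those pairs of talOcc3 were thus kept in neither other annotation, and the later mole assembly did not bear out these differences from the mouse. CYP26B1 did not enter the comparison with the later assembly. Percentiles ran from 26.5 to 90.5. Over the 24 percentiles of the planned comparisons (several loci, space and order against both annotations), 5 lay outside the middle 95% of random lists. By chance 1.2 would, a number that is only approximate for shares with many ties, and the lists shared 3 genes. The 5 include the several-loci percentiles of the ovary and FGF lists, which lay outside only because ties were split equally to each side. The others were the space percentiles of the ovary, testis and FGF lists.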

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

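No paired analysis was possible because the file carries no per-sample values. The planned expression alternatives were not run for the same reason. Library depth is unknown and entered no calculation here. Whether it bears on which genes have a model cannot be told, since how the models were made is not given. Of 153 values that an alternative could change, 123 kept their side of the 95% range or stayed within their interval or 1.5 times the count, and 0 reversed. Another 27 values were fixed by construction, since tandem distance enters only tandem counts and matching only percentiles. The 4 gaps at FGF9 and CYP17A1 were not tested by naming coding neighbours, since their nearest loci already had a symbol and a coding part. A further 3 alternatives changed no model and so tested nothing: uniting coding parts, requiring a coding part and not merging overlapping loci. Ignoring orientation was not an alternative for the later assembly, whose strand was not used. The space percentiles of the ovary, testis and FGF lists stayed above the middle 95% of random lists under each of their alternatives, the lowest being 98.1 (FGF ligands, same-strand neighbours). Same-strand neighbours, fewer by construction, raised the medians of all 6 lists. The ovary median rose to 680 kb, beyond its interval, while those of testis genes (498 kb) and FGF ligands (326 kb) stayed within theirs. The medians of germ cell genes and of markers of other cell types also left their intervals. On scaffolds annotated to 1000000 or beyond, median coding length was 1104 and median exons 6. With names as written, which leaves copies with separate names, 70 symbols had several loci and 27 were tandem. With scores of at least 50% of the highest, 1351 symbols had several loci and 691 were tandem; with more than 1 exon, 1424 had several loci. These last 2 alternatives were chosen after seeing the data, as was the set of genes named once in both species, in which the Leydig space percentile rose to 99.2; that set drops 4 Leydig members. The low percentiles of the ovary and FGF lists for several loci ended in each of these: 47.3 and 47.2 with names as written, 3.31 and 3.27 with at least 300 coding bases, 8.21 and 3.98 by score, 7.63 and 9.68 by exons. Both lists have 0 such members, so the percentile follows the share among other genes. The low values of the main setting lay below the middle 95% only because ties were split equally to each side. Pairs kept in mouse rose to 94.6% with up to 3 genes between and 93.9% with orientation ignored, and in the later assembly to 98.8% with up to 3 genes between; these alternatives are looser by construction.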

Other observations

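The tests on CYP17A1 and on RUBCNL beside FGF9 were chosen after the result was seen. The comparisons of scores, families, Y-linked genes and space with the mouse were added after seeing the data, although the predictions for the genome-wide pairs and for space in mouse were written before their values were.

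Score per aligned reference base lay outside the middle 95% of random lists in 4 of the 6 lists. Its median was 1.25 over 16190 scored symbols. FGF ligands had a median of 1.51, above all random lists, and testis and Sertoli genes 1.43 (percentile 99.6). Leydig and steroidogenesis genes had 1.03 (percentile 0.89) and germ cell and meiosis genes 1.06 (quartiles 0.725 and 1.36, percentile 0.685), from 0.471 at TNP2 and 0.495 at REC8 to 1.49 at DAZL and 1.60 at DMC1. Ovary and granulosa genes had 1.31 (percentile 73.1) and markers of other cell types 1.09 (percentile 13.4). What the score counts is not given in the sources used here.

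Y-linked genes lay on scaffolds annotated over short stretches; scaffold lengths were not measured. SRY, the testis-determining gene, was a single exon of 582 coding bases on scaffold 83, whose last annotated base was 141938. USP9Y, DDX3Y and UTY shared scaffold 62, and EIF1AY and the best KDM5D locus scaffold 69. A second KDM5D locus, of 2 exons and 291 coding bases, lay on a scaffold with its last annotated base at 1726. Loci named after 9 mitochondrial genes numbered 433, of which 431 were single exons, and 6 lay on scaffolds annotated to 1000000 or beyond. Ribosomal protein symbols had 504 loci, 77.2% with a single exon.

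FGF9 lay next to RUBCNL in the mole and 16.9 Mb from it in the mouse. A misjoin in the talOcc3 assembly alone is argued against by the later mole assembly, where 0 protein-coding loci separate the pair. Across 11691 genes in the 3 annotations, 675 adjacent mole pairs were not adjacent in mouse, and 37.2% of these (95% interval 33.5 to 41.0%) were not adjacent in the later assembly either, against 1.23% of pairs adjacent in mouse. Differences made by the talOcc3 assembly or its gene models alone thus do not account for most such pairs, but may account for that share. A join error carried into both assemblies stays open, as does whether the change arose in the mouse or the mole lineage, since no further species was used here.

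The 3 CYP17A1 loci have several exons each, at least 6, which argues against spliced copies put back into the genome. Between the full-length models 2 of the 7 introns differ by more than 10%, at most by 33.5% (990 against 1435 bases and 930 against 618). The other 5 differ by 0 to 2.94%. The full-length models are thus not the same sequence entered 2 times. Whether 1 locus was assembled more than once in differing versions cannot be told apart from a true tandem, since intron lengths alone do not decide it. A tandem made by the talOcc3 assembly alone also stays open, because the 2 protein-coding loci and 2 pseudogenes between BORCS7 and WBP1L in the later assembly carry no gene symbol. The wider WBP1L to BORCS7 interval, a log2 ratio of 1.04 to mouse, lay at percentile 88.6 among 11206 kept pairs. An added gene dose in the mole is a hypothesis that expression values would have to test.

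Wide space around ovary and granulosa, testis and Sertoli and FGF genes was found in the mouse too. Over 12299 genes with both neighbours in both species, the lists lay at mouse percentiles of 100, 100 and 98.21, so gene models missing from the mole annotation alone do not account for it. The median log2 ratio of mole to mouse space was 0.01, -0.09 and -0.04, at percentiles 66.0, 44.8 and 51.4 among random lists. No widening in the mole beyond that of random lists was thus detectable for these lists. The measures were unlike: mole space used gene lines with every model as neighbour, and mouse space coding spans with protein-coding neighbours only. How small a widening this ratio could detect was not simulated. In this gene set the Leydig list lay at percentile 99.2 in the mole, against 86.9 over all its members, and 90.9 in the mouse. The set leaves out 3 members with several loci and CYP21A2, which has 1 locus and 4.11 kb of space. With the 6 score percentiles, 24 list percentiles were added in this section after seeing the data, of which 11 lay outside the middle 95%. The added alternatives on score and exon number are not among the 24. Of the 11, 7 were space percentiles, and those of the mole repeat the planned comparison on part of the same genes. The 11 are therefore not separate results to set against the 1.2 expected by chance. The added percentiles share genes and are not independent. No biological explanation was tested.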
